A study of Mus musculus with 68 samples.

How the data were processed

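The starting point was 2 deposited tables of raw read counts, for the 38 libraries of the stage series and the 30 of the knockout series, with the same 24059 gene symbols. Per the submitters' processing notes reads were aligned with STAR 2.5.2b to mouse build mm10 and counted with HTSeq. The labels name a stranded total RNA kit for low input. Values were whole numbers with differing totals and were used as counts unchanged. The gene annotation, the strand setting and the number of raw reads are not given in the sources used here. Of the symbols 22548 matched a RefSeq symbol and 1372 matched only a synonym. The 13 protein genes of mitochondrial DNA, several constant genes of immunoglobulins and 3 members of the globin list were absent from the tables, so the mitochondrial list could not be tested.

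Libraries were grouped by stage and genotype as labelled. The label ERY-III-VI goes with a source name of polychromatic and orthochromatic cells and is used as written. Groups compared were each pair of neighbouring stages, ERY-IV against BFU-E, GS-KO against WT within each gate, and CFU-E against BFU-E within WT of the knockout series. Each comparison had its own fit on its own libraries in edgeR 4.0.16 (R 4.3.3), with genes kept by filterByExpr (minimum count 10, minimum total 15), TMM scaling and the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Standard errors of log2 fold changes are the fold change over the square root of F. Values in counts per 1000000 (CPM) are relative to library totals and are given as mean ± SD. The interaction of genotype with the 5 gates was tested with 4 degrees of freedom over all 30 knockout libraries.

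Gene lists of 38 kinds were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and the alternatives listed first below. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log CPM (prior count 1) with a preset correlation of 0.01, with Benjamini-Hochberg over the lists of a comparison, and again with the correlation estimated from the residuals. Of 495 list tests over the 14 comparisons 215 were called with the preset value and 47 with the estimated one. None of the calls in the 8 stage comparisons held with the estimated correlation, and those that held were 10 in GS-KO BFU-E, 6 in CFU-E, 7 in ERY-I-II, 9 in ERY-III-VI, 8 in ERY-V-VI and 7 in WT CFU-E against BFU-E. Where the text gives no estimated-correlation p beside a called list, the call held at an adjusted p under 0.05. A second test, fry, called 297, and it asks whether the members move on balance one way, without setting them against other genes. Its mixed form asks whether they move in either direction.

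Genes named are Glul and 16 landmark genes, of which 1 is not reported here, the 6 highest and 6 lowest fold changes among called genes of at least 2-fold with a mean of at least 5 CPM and no overlap between the groups, and list members with the largest fold change or the smallest adjusted p. The planned landmarks Hbb-bs and Hbb-bt are absent from the tables, and Hbb-b1 is given in their place, a choice made after seeing the data. Genes whose call changed direction under any setting or ended when 1 library was left out were not used as examples, except Hbb-b1 in GS-KO ERY-III-VI, added after its values were seen. Fold changes of genes with 3 or fewer counts in a group were not given. Counting error does not cover reads copied by PCR, since no molecular tags are described.

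Simulated log2 changes of 1 and 2 were found in 4.76 and 55.6% of cases with 11 libraries at the spread of ERY-I and ERY-II, 30.2 and 75.8% with 8 of ERY-II and ERY-III, 38.1 and 79.4% with 6 of GS-KO and WT ERY-V-VI, and 92.4 and 100% with 6 of GS-KO and WT CFU-E. False calls were 1.85, 2.25, 4.92 and 7.69% of all calls, the last above the 5% aimed at. Rates under the sample structure below were not tested.

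Same-numbered libraries were checked for shared deviations from their group means. They went together in ERY-III and ERY-II (lowest correlation 0.60), in ERY-IV and ERY-III (0.34) and in ERY-I and CFU-E (0.31), where the numbers also follow the 2 library sets, and there the number was taken as a pairing. Xist-positive libraries of ERY-I and ERY-II, ERY-IV and ERY-V, and ERY-V and ERY-VI went together by position instead. The labels do not say what the numbers share.

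Alternatives were DESeq2 1.42.0, RLE size factors, library totals without TMM, the globin genes and the 10 most abundant genes left out, no low-count filter, a stricter filter of a mean of 5 CPM, limma-voom with quality weights, the replicate number as a block, all groups of a series in 1 fit, and leaving out each library in turn. Chosen after seeing the data were triplicates summed to 1 library, only Y-positive or only Xist-positive libraries, the latter also with their position in the gate as a block for ERY-II against ERY-I, ERY-V against ERY-IV and ERY-VI against ERY-V, the library set as a term, summed triplicates of the knockout series with the spread of the Xist-positive stage libraries (edgeR likelihood ratio test), and the knockout comparisons without 721 genes that followed the neutrophil markers (listed, or correlated over 0.7 with them within groups of 24 Xist-positive stage libraries). No library was left out of the results given first. Strand, splicing and reads outside the gene tables were not analysed here.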

Results

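RNA was sequenced from erythroid cells enriched by flow cytometry from mouse bone marrow, in 68 libraries that form 2 series. The stage series holds 38 libraries of 8 populations, with 3 libraries of BFU-E (the earliest committed erythroid progenitor), 5 of CFU-E (the progenitor that follows it), 7 of ERY-I, 4 each of ERY-II, ERY-III and ERY-IV, 7 of ERY-V and 4 of ERY-VI, the ERY numbers running from less to more mature gates. The knockout series holds 30 libraries, 3 of wild type (WT) and 3 of GS-KO in each of BFU-E, CFU-E, ERY-I-II, ERY-III-VI and ERY-V-VI. The labels do not spell out GS, which is taken here as glutamine synthetase, the enzyme encoded by Glul that joins ammonium to glutamate. Total counts per library ran from 1630863 to 11472763 in the stage series and from 3131142 to 15806844 in the knockout series, and the number of genes with a count from 5102 in an ERY-VI library to 15061 in a GS-KO CFU-E library.

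The mean share of counts in globin genes was 0.0053% in BFU-E, 4.03% in ERY-I, 28.9% in ERY-II, 23.9% in ERY-III, 32.6% in ERY-IV, 36.3% in ERY-V and 64% in ERY-VI. The libraries of the stage series fell into 2 sets, 12 with transcripts of Y-linked genes (replicates 1 to 3 of BFU-E, CFU-E, ERY-I and ERY-V) and 26 with Xist, the transcript of the inactive X chromosome. All 30 knockout libraries had Y-linked transcripts. The ratio of Hbb-b1 to Hba-a1, the major adult globins, averaged 1.37 in the Y-positive ERY-I libraries (n = 3) and 4.34 in the Xist-positive ones (n = 4). Whether same-numbered libraries are separate mice is not stated, so p-values measure only the spread between libraries, which may be technical. For gene lists the numbers of members called are also given with adjustment within the list, and the camera test is repeated with a correlation between genes estimated from the data.

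CFU-E were compared with BFU-E, the step between the 2 progenitors. Tfrc, the transferrin receptor that brings iron into the cell, rose from 245 ± 3.72 to 1070.5 ± 234 counts per 1000000 (CPM, mean ± SD, n = 3 and 5), while Kit, the stem cell factor receptor, fell from 946 ± 10.3 to 404 ± 149.8 CPM and Gata2, a progenitor transcription factor, from 404 ± 2.71 to 34.6 ± 19.8 CPM. Of the genes tested 1964 genes were higher and 2067 lower in CFU-E out of 10807 (edgeR, Benjamini-Hochberg adjusted p below 0.05). In log2 fold change ± SE, large rises among genes of at least 5 CPM without overlap between the groups were those of Ppap2a (6.07 ± 0.95) and Btnl10 (6.04 ± 0.77), and large falls were those of Vim (-7.13 ± 0.15) and Scin (-6.78 ± 0.37), which encode an intermediate filament and an actin-severing protein. Progenitor genes fell. 18 of 19 stem and progenitor genes fell (18 within the list, camera adjusted p = 6.0e-08, estimated-correlation adjusted p = 0.23), with Meis1 (-5.99 ± 0.41), Spi1 (-4.60 ± 0.62) and Erg (-4.21 ± 0.64). Genes of red cell function went the other way. 12 of 14 heme synthesis genes rose (12 within the list, camera adjusted p = 2.2e-06, estimated-correlation adjusted p = 0.28), among them the pathway enzymes Uros (2.52 ± 0.47) and Cpox (1.67 ± 0.13). 15 of 21 erythroid membrane genes rose (15 within the list, camera adjusted p = 1.7e-06, estimated-correlation adjusted p = 0.18), among them the dematin and beta spectrin genes Dmtn (3.78 ± 0.64) and Sptb (3.34 ± 0.24). 10 of 19 iron handling genes rose and 1 fell (13 and 1 within the list, camera adjusted p = 0.0032, estimated-correlation adjusted p = 0.34), with Fth1 (1.76 ± 0.35) and Glrx5 (1.17 ± 0.20). Cell division genes rose. 23 of 30 DNA replication genes rose (26 within the list, camera adjusted p = 1.2e-07, estimated-correlation adjusted p = 0.27), for example Rrm2 (2.48 ± 0.27) and Cdt1 (1.07 ± 0.12). 18 of 30 mitosis genes rose (19 within the list, camera adjusted p = 1.9e-06, estimated-correlation adjusted p = 0.18), for example Aurka (1.33 ± 0.30) and Ccna2 (1.33 ± 0.20).

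Mitochondrial and amino acid genes also rose in CFU-E. 29 of 40 nuclear-encoded respiratory chain genes rose (37 within the list, camera adjusted p = 6.0e-08, estimated-correlation adjusted p = 0.38), with Ndufa5 (1.19 ± 0.23) and Cox5a (1.13 ± 0.21). 18 of 24 TCA cycle genes rose and 1 fell (19 and 1 within the list, camera adjusted p = 3.8e-06, estimated-correlation adjusted p = 0.23), with Idh3a (1.10 ± 0.15) and Cs (0.87 ± 0.12). In glutamine metabolism 11 of 23 glutamine and glutamate enzyme genes rose and 2 fell (13 and 2 within the list, camera adjusted p = 0.0097, estimated-correlation adjusted p = 0.20), led by Asns (2.22 ± 0.27) and Gls2 (1.94 ± 0.39), while Glul itself was at 114 ± 0.791 and 99.9 ± 5.78 CPM and passed no threshold (adjusted p = 0.74). Stress response members rose too. 13 of 22 integrated stress response genes rose and 1 fell (13 and 1 within the list, camera adjusted p = 2.7e-04, estimated-correlation adjusted p = 0.23), for example Mthfd2 (1.66 ± 0.23) and Sesn2 (1.18 ± 0.24). 11 of 25 NRF2 target and antioxidant genes rose and 2 fell (11 and 2 within the list, camera adjusted p = 0.0045, estimated-correlation adjusted p = 0.23), for example Prdx2 (1.72 ± 0.35) and Gclc (1.01 ± 0.12). Markers of other lineages fell. 6 of 9 megakaryocyte and platelet marker genes fell (6 within the list, camera adjusted p = 0.011, estimated-correlation adjusted p = 0.18), with Itga2b (-2.96 ± 0.34) and Nrgn (-2.51 ± 0.19). 4 of 4 mast cell, basophil and eosinophil marker genes fell (4 within the list, camera adjusted p = 0.0045, estimated-correlation adjusted p = 0.18), with Siglec5 (-5.97 ± 0.42) and Cpa3 (-5.18 ± 0.43). Replicates 1 to 3 of both populations were closer to each other than Xist-positive libraries of one gate were, and the count of changed genes was 7303 in these Y-positive libraries alone, 2291 to 2318 without BFU-E replicate 1, 2 or 3 and 105 with each triplicate summed to 1 library. With library totals 1438 genes were higher and 2389 lower, the median of all genes moving from -0.01 to -0.14.

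The same step was measured again in the WT libraries of the knockout series (n = 3 and 3), where 3737 genes were higher and 3895 lower in CFU-E of 10826 tested. Library totals gave 2858 higher and 4791 lower with the median of all genes moving from -0.03 to -0.13. Of 10561 genes tested in both series 3773 were called in both, against 2789.7 expected by chance, and 100% of them had the same sign (Pearson r 0.90 and Spearman rho 0.83 across genes, which are not independent replicates). Gata2 fell from 335 ± 4.41 to 38.9 ± 1.08 CPM and Tfrc rose from 299 ± 2.46 to 915 ± 11.9 CPM. Again 13 of 14 heme synthesis genes rose (13 within the list, camera adjusted p = 2.4e-06), with Uros (1.65 ± 0.10) and Ppox (1.53 ± 0.12). 16 of 21 erythroid membrane genes rose and 1 fell (16 and 2 within the list, camera adjusted p = 6.9e-06), with Sptb (3.82 ± 0.04) and Dmtn (3.05 ± 0.15). 30 of 30 mitosis genes rose (30 within the list, camera adjusted p = 1.3e-09), with Ccna2 (1.05 ± 0.03) and Plk1 (0.94 ± 0.05). 27 of 30 DNA replication genes rose (28 within the list, camera adjusted p = 4.7e-09), with Rrm2 (1.84 ± 0.04) and Clspn (1.08 ± 0.03). 1 of 19 stem and progenitor genes rose and 18 fell (1 and 18 within the list, camera adjusted p = 6.3e-07), with Erg (-5.75 ± 0.35) and Meis1 (-5.08 ± 0.19). 38 of 40 nuclear-encoded respiratory chain genes rose (38 within the list, camera adjusted p = 8.6e-09), with Ndufa5 (0.81 ± 0.05) and Ndufs1 (0.69 ± 0.03). 21 of 24 TCA cycle genes rose and 2 fell (21 and 2 within the list, camera adjusted p = 6.1e-05), with Pcx (1.40 ± 0.12) and Idh3a (0.77 ± 0.03). Of amino acid genes 11 of 17 amino acid transporter genes rose and 4 fell (11 and 4 within the list, camera adjusted p = 0.021, estimated-correlation adjusted p = 0.27), with Slc25a12 (1.03 ± 0.07) and Slc38a5 (0.87 ± 0.05). 2 of 4 ammonium transport and urea cycle genes rose and 1 fell (2 and 1 within the list, camera adjusted p = 0.34), with Nags (2.61 ± 0.28) and Rhag (1.90 ± 0.05). In the response to erythropoietin 3 of 12 erythropoietin-STAT5 response genes rose and 8 fell (3 and 8 within the list, camera adjusted p = 0.40), with the negative regulator Cish (-2.95 ± 0.32) lower and the receptor gene Epor (0.67 ± 0.06) higher. Survival and damage genes split. 8 of 14 apoptosis regulator genes rose and 4 fell (8 and 4 within the list, camera adjusted p = 0.25, median 0.28, mean -0.18, camera direction up), with Bcl2 (-4.14 ± 0.18) and Bcl2l11 (1.52 ± 0.08). 7 of 20 p53 target genes rose and 10 fell (7 and 10 within the list, camera adjusted p = 0.79), with Xpc (-1.29 ± 0.07) and Sesn2 (0.90 ± 0.13).

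ERY-I were compared with CFU-E, the step into morphologically recognisable precursors. Alas2, the first enzyme of heme synthesis in red cells, rose from 10.5 ± 1.21 to 1588 ± 539 CPM and Slc4a1, the band 3 anion exchanger, from 35.1 ± 41.8 to 6838 ± 2904 CPM (n = 5 and 7), while Kit fell to 56.3 ± 33.7 CPM. Of 10460 genes tested 2660 were higher and 2190 lower in ERY-I, and Glul rose by 0.96 ± 0.17. Red cell genes rose. 4 of 4 globin genes rose (4 within the list, camera adjusted p = 3.1e-04, estimated-correlation adjusted p = 0.33), with Hbb-b1 (8.80 ± 1.32) and Hba-a2 (8.41 ± 0.78). 12 of 14 heme synthesis genes rose and 1 fell (13 and 1 within the list, camera adjusted p = 1.6e-05, estimated-correlation adjusted p = 0.34), with Alas2 (7.69 ± 0.45) and Slc25a37 (5.65 ± 0.43). 21 of 22 erythroid membrane genes rose (22 within the list, camera adjusted p = 3.6e-10, estimated-correlation adjusted p = 0.33), with Slc4a1 (8.04 ± 0.91) and Tmod1 (6.95 ± 0.60). 12 of 20 erythroid transcription factor genes rose and 3 fell (13 and 3 within the list, camera adjusted p = 8.6e-04, estimated-correlation adjusted p = 0.34), with Sox6 (4.90 ± 0.50) and E2f2 (3.99 ± 0.46). Mitosis genes rose together with brakes on the cell cycle. 30 of 30 mitosis genes rose (30 within the list, camera adjusted p = 6.6e-13, estimated-correlation adjusted p = 0.33), with Cenpf (2.67 ± 0.44) and Mki67 (2.56 ± 0.43). 10 of 13 cell cycle inhibitor genes rose and 1 fell (10 and 1 within the list, camera adjusted p = 3.1e-04, estimated-correlation adjusted p = 0.33), with Btg2 (4.86 ± 0.78) and Ccng2 (4.70 ± 0.81).

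Genes for making ribosomes and nucleotides fell in ERY-I. 25 of 25 ribosome biogenesis genes fell (25 within the list, camera adjusted p = 5.8e-11, estimated-correlation adjusted p = 0.33), with Wdr12 (-2.04 ± 0.28) and Rrp9 (-2.02 ± 0.37). 2 of 23 purine and pyrimidine synthesis genes rose and 15 fell (2 and 15 within the list, camera adjusted p = 8.7e-06, estimated-correlation adjusted p = 0.33), with Atic (-1.55 ± 0.22) and Cad (-1.39 ± 0.21). 1 of 11 heat shock genes rose and 8 fell (1 and 8 within the list, camera adjusted p = 0.0039, estimated-correlation adjusted p = 0.33), with Hspd1 (-1.51 ± 0.25) and Hsp90ab1 (-0.92 ± 0.18). 3 of 22 glutamine and glutamate enzyme genes rose and 12 fell (3 and 13 within the list, camera adjusted p = 0.0032, estimated-correlation adjusted p = 0.33), with Oat (-1.46 ± 0.17) and Psat1 (-1.32 ± 0.25). In the other direction 18 of 25 autophagy and mitochondrial clearance genes rose and 3 fell (20 and 3 within the list, camera adjusted p = 3.1e-04, estimated-correlation adjusted p = 0.34), with Atg4a (2.27 ± 0.38) and Gabarapl2 (1.69 ± 0.46). 13 of 22 late erythroid ubiquitin-proteasome genes rose and 1 fell (13 and 2 within the list, camera adjusted p = 0.0012, estimated-correlation adjusted p = 0.46), with Ube2o (3.57 ± 0.35) and Ube2h (3.44 ± 0.36). 9 of 15 interferon response genes rose (10 within the list, camera adjusted p = 0.0051, estimated-correlation adjusted p = 0.49), with Rsad2 (5.44 ± 0.37) and Isg15 (3.41 ± 0.49). Markers of other cell types rose with these groups. 9 of 9 neutrophil marker genes rose (9 within the list, camera adjusted p = 0.044, estimated-correlation adjusted p = 0.62), with S100a9 (8.82 ± 2.18) and Ngp (8.98 ± 2.29). 15 of 16 monocyte and macrophage marker genes rose (15 within the list, camera adjusted p = 8.6e-04, estimated-correlation adjusted p = 0.56), with Lyz2 (8.90 ± 2.07) and Ctss (8.35 ± 1.67). 10 of 10 B cell marker genes rose (10 within the list, camera adjusted p = 0.011, estimated-correlation adjusted p = 0.58), with Spib (7.44 ± 1.81) and Ebf1 (8.52 ± 1.90). Summed neutrophil markers reached 16008 to 16430 CPM in the Y-positive ERY-I libraries, and the call of the neutrophil list was lost without ERY-I replicate 1, 2, 3 or 5 (adjusted p = 0.051 to 0.10), that of the macrophage list without ERY-I replicate 1, 2, 3, 4 or 5 (adjusted p = 0.13 to 0.38) and that of the B cell list without ERY-I replicate 1, 2, 3, 4 or 5 (adjusted p = 0.16 to 0.27). The count was 9091 within the Y-positive libraries, 4271 within the Xist-positive ones and 6342 with library set as a term. Library totals gave 1690 higher and 3475 lower genes, with the median of all genes moving from 0.05 to -0.30.

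ERY-II were compared with ERY-I. Hba-a1, an alpha-globin gene, rose from 5883 ± 4123 to 33100.0 ± 5644 CPM, Bnip3l, a receptor for the removal of mitochondria, from 259 ± 50.7 to 1031 ± 303 CPM and Glul from 147 ± 15.6 to 251 ± 32.2 CPM (n = 7 and 4). Of 10327 genes tested 2091 were higher and 2588 lower. The median of all genes lay at -0.35 with TMM and at -1.68 with library totals, which gave 423 higher and 6998 lower, so that changes here are relative to the TMM scale. Red cell genes rose further. 22 of 22 erythroid membrane genes rose (22 within the list, camera adjusted p = 6.7e-12, estimated-correlation adjusted p = 0.48), with Epb4.1 (3.67 ± 0.37) and Mpp1 (2.75 ± 0.35). 12 of 14 heme synthesis genes rose and 1 fell (12 and 1 within the list, camera adjusted p = 2.5e-05, estimated-correlation adjusted p = 0.48), with Fech (2.85 ± 0.40) and Urod (1.88 ± 0.33). 13 of 20 erythroid transcription factor genes rose and 3 fell (13 and 4 within the list, camera adjusted p = 9.4e-04, estimated-correlation adjusted p = 0.48, list median -0.09 with library totals against 1.21), with Trim58 (3.21 ± 0.32) and Klf3 (2.32 ± 0.40). 30 of 30 mitosis genes rose (30 within the list, camera adjusted p = 3.4e-13, estimated-correlation adjusted p = 0.48), with Ube2c (2.58 ± 0.42) and Nusap1 (2.18 ± 0.31). 7 of 13 cell cycle inhibitor genes rose and 1 fell (7 and 1 within the list, camera adjusted p = 0.0081, estimated-correlation adjusted p = 0.48, list median -0.09 with library totals against 1.20), with Cdkn2d (2.87 ± 0.31) and Gadd45a (2.73 ± 0.31). Clearance genes rose. 17 of 25 autophagy and mitochondrial clearance genes rose and 1 fell (17 and 1 within the list, camera adjusted p = 3.0e-06, estimated-correlation adjusted p = 0.48), for example Gabarapl2 (3.35 ± 0.38) and Pink1 (2.99 ± 0.41). 14 of 22 late erythroid ubiquitin-proteasome genes rose and 1 fell (14 and 1 within the list, camera adjusted p = 2.0e-06, estimated-correlation adjusted p = 0.48), for example Ube2h (3.90 ± 0.41) and Ube2o (3.77 ± 0.42). Biosynthetic genes fell. 24 of 25 ribosome biogenesis genes fell (24 within the list, camera adjusted p = 6.2e-08, estimated-correlation adjusted p = 0.48), for example Rrp12 (-3.09 ± 0.53) and Pes1 (-2.82 ± 0.44). 1 of 23 purine and pyrimidine synthesis genes rose and 14 fell (1 and 15 within the list, camera adjusted p = 1.9e-04, estimated-correlation adjusted p = 0.48), for example Cad (-3.30 ± 0.36) and Atic (-2.89 ± 0.46). In sugar metabolism 3 of 17 glycolysis genes rose and 9 fell (3 and 9 within the list, camera adjusted p = 0.17), with falls of Pklr (-3.26 ± 0.17) and Ldha (-2.69 ± 0.62) and a rise of Bpgm, which makes the regulator of hemoglobin's oxygen affinity, by 4.33 ± 0.43. Summed neutrophil markers were at 16008 to 16430 CPM in the 3 Y-positive ERY-I libraries, 2.04 to 1404 in the 4 Xist-positive ones and 5.79 to 2326 in ERY-II. 0 of 19 neutrophil and 0 of 20 macrophage genes passed the threshold (camera adjusted p = 0.48 and 0.69). ERY-II libraries were all Xist-positive, and within that set the count was 4086.

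ERY-III were compared with ERY-II (n = 4 and 4), where the count depended on the pairing. Same-numbered libraries of the 2 stages were alike (lowest correlation 0.60), and with the replicate number as a block 368 of 7574 genes were higher and 410 lower. Without it 14 were higher and 0 lower by edgeR, 949 had an unadjusted p below 0.05, and DESeq2 called 173 higher and 102 lower. The 14 calls ended (0 genes) with RLE size factors, with library totals, with the abundant genes left out, with all groups in 1 fit and when any 1 of the 8 libraries was left out. DNA replication genes moved up together. 0 of 30 DNA replication genes passed the test (29 higher and 0 lower within the list, camera adjusted p = 1.9e-19, estimated-correlation adjusted p = 0.97), and with the block 28 of the 30 rose (camera adjusted p = 5.3e-15). The median of all genes moved from -0.02 to 0.15 with library totals. Alas2 stood at 8370.5 ± 1669 and 5919.8 ± 826 CPM and Glul at 251 ± 32.2 and 201.2 ± 14.9 CPM. Neither passed without the block (adjusted p = 0.43 and 0.41). Histone genes took 2.88 ± 0.577% of counts in ERY-II and 6.05 ± 0.737% in ERY-III.

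ERY-IV were compared with ERY-III (n = 4 and 4), where cell division genes fell and clearance genes rose. Glul rose from 201.2 ± 14.9 to 322 ± 36.6 CPM and Bnip3l from 622 ± 87.7 to 1099 ± 118 CPM. Of 7238 genes tested 749 were higher and 238 lower, and 1167 and 657 with the replicate number as a block, since same-numbered libraries were alike (lowest correlation 0.34). Large rises were those of Mettl20 (3.41 ± 0.45) and Xpo7 (2.66 ± 0.45), of which Xpo7 encodes a nuclear export receptor, and large falls those of the nuclear import and cell cycle genes Kpna2 (-1.82 ± 0.24) and Cdc25c (-1.62 ± 0.24). 19 of 30 mitosis genes fell (27 within the list, camera adjusted p = 5.5e-11, estimated-correlation adjusted p = 0.91), with Plk1 (-1.57 ± 0.29), Ccnb1 (-1.57 ± 0.25) and Cdc20 (-1.36 ± 0.24). 13 of 22 autophagy and mitochondrial clearance genes rose (14 within the list, camera adjusted p = 1.2e-05, estimated-correlation adjusted p = 0.91), with Ulk1 (2.17 ± 0.33) and Atg14 (1.91 ± 0.29). 11 of 22 late erythroid ubiquitin-proteasome genes rose and 1 fell (12 and 2 within the list, camera adjusted p = 5.8e-04, estimated-correlation adjusted p = 0.91), with Fbxo30 (1.98 ± 0.25) and Ube2h (1.87 ± 0.35). 8 of 22 erythroid membrane genes rose (13 within the list, camera adjusted p = 1.5e-05, estimated-correlation adjusted p = 0.91), with Kel (0.87 ± 0.18). The count of changed genes was 521 to 641 without ERY-III replicate 1, 2 or 3 or ERY-IV replicate 3, and with library totals 156 genes were higher and 478 lower, the median of all genes moving from -0.07 to -0.63.

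ERY-V were compared with ERY-IV (n = 7 and 4). Bnip3l rose from 1099 ± 118 to 2846 ± 737 CPM, and Klf1, a master regulator of red cell genes, changed by -1.52 ± 0.33. Of 6990 genes tested 454 were higher and 163 lower. Large rises among genes of at least 5 CPM without overlap between the groups were those of Bpgm (2.81 ± 0.40) and Ccndbp1 (2.64 ± 0.36), and large falls those of the replication-dependent histone genes Hist1h4n (-2.71 ± 0.45) and Hist2h4 (-2.59 ± 0.32). 15 of 29 DNA replication genes fell (18 within the list, camera adjusted p = 3.2e-11, estimated-correlation adjusted p = 0.58), with Pcna (-1.89 ± 0.35) and Rrm1 (-1.59 ± 0.32). 1 of 30 mitosis genes rose and 10 fell (2 and 21 within the list, camera adjusted p = 1.6e-06, estimated-correlation adjusted p = 0.58), with Birc5 (-1.40 ± 0.29). 9 of 21 autophagy and mitochondrial clearance genes rose (12 within the list, camera adjusted p = 1.7e-05, estimated-correlation adjusted p = 0.58), with Becn1 (1.91 ± 0.32) and Bnip3l (2.33 ± 0.37). 9 of 22 late erythroid ubiquitin-proteasome genes rose (10 higher and 3 lower within the list, camera adjusted p = 8.6e-04, estimated-correlation adjusted p = 0.58, list median -0.20 with library totals against 0.70), with Rnf10 (2.35 ± 0.38) and Ube2o (2.34 ± 0.41). Also raised were Ncoa4 (2.16 ± 0.35) and Iscu (2.03 ± 0.36) of iron handling. Markers of other cells were called as well. 15 of 18 neutrophil marker genes rose (18 within the list, camera adjusted p = 1.8e-08, estimated-correlation adjusted p = 0.58). 2 of 16 monocyte and macrophage marker genes rose (2 within the list, camera adjusted p = 0.0013, estimated-correlation adjusted p = 0.58). Neither list was called within the Xist-positive libraries (adjusted p = 0.19 and 0.15), and with their position as a block only the macrophage one was (0.087 and 0.0095). Summed neutrophil markers were at 3233 to 3292 CPM in ERY-V replicates 1 to 3, 3834 in replicate 5 and 1.51 to 134 in the other 3. The count of changed genes was 127 to 390 without any 1 of the ERY-IV libraries or ERY-V replicate 1, 2, 3 or 5, 971 without ERY-V replicate 7, 406 within the Xist-positive libraries, 1020 in these with their position as a block and 315 with ERY-V replicates 1 to 3 summed. With all groups in 1 fit 900 genes were higher and 1357 lower, and with library totals 53 and 358, the median of all genes moving from 0.06 to -0.72.

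ERY-VI, the most mature gate, were compared with ERY-V (n = 4 and 7). Alas2 rose from 19363 ± 3409.5 to 31061 ± 4212 CPM and Hba-a1 from 57242 ± 14367 to 97952 ± 4279.9 CPM, on a scale where only 5030 genes could be tested and the median of all genes lay at -0.34. Of these 167 were higher and 227 lower. Higher genes included Hba-a2 (2.34 ± 0.46), Alas2 (2.41 ± 0.34), Gabarapl2 (2.16 ± 0.41) and Bnip3l (2.08 ± 0.33), the ferritin light chain gene Ftl1 (2.29 ± 0.42) and Ube2l6 (2.07 ± 0.30) and Bpgm (2.14 ± 0.34). Lower genes included the transcription factors Tal1 (-1.68 ± 0.39) and Sox6 (-1.44 ± 0.28), the heme transporter gene Abcb10 (-2.22 ± 0.39) and Cenpf (-2.13 ± 0.50) and Btg2 (-1.91 ± 0.40). 2 of 4 globin genes rose (4 within the list, camera adjusted p = 5.0e-05, estimated-correlation adjusted p = 0.67). 5 of 33 cytosolic ribosomal protein genes rose (12 within the list, camera adjusted p = 1.1e-11, estimated-correlation adjusted p = 0.68, list median -0.31 with library totals against 1.26), with Rplp1 (1.97 ± 0.37). Summed neutrophil markers were at 3.36 to 930 CPM in ERY-VI. 0 of 18 neutrophil and 0 of 15 macrophage genes passed the threshold (camera adjusted p = 0.83 and 0.91). With library totals 7 genes were higher and 2212 lower and the median was -2.24. The count of changed genes was 182 to 239 without ERY-VI replicate 1 or ERY-V replicate 1, 2, 3 or 5, 59 within the Xist-positive libraries (48 higher and 11 lower), 211 in these with their position as a block (117 and 94) and 75 with ERY-V replicates 1 to 3 summed (59 and 16). The balance of directions thus depended on the fit, with 173 higher and 102 lower with the replicate number as a block and 468 and 2872 with all groups in 1 fit.

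ERY-IV were also set against BFU-E, the 2 ends of the nucleated series with deep libraries (n = 4 and 3), although the 4 ERY-IV libraries were Xist-positive and the 3 BFU-E libraries Y-positive, so that stage and library set cannot be told apart. Slc4a1 went from 15.4 ± 11.2 to 21369 ± 2133 CPM and Kit from 946 ± 10.3 to 0.436 ± 0.726 CPM. Of 10675 genes tested 3361 were higher and 4765 lower, the median of all genes lying at -0.50. Library totals gave 1082 higher and 8136 lower with the median at -2.70. Red cell genes rose. 4 of 4 globin genes rose (4 within the list, camera adjusted p = 0.0013, estimated-correlation adjusted p = 0.39), with Hbb-b1 (15.60 ± 1.20). 13 of 14 heme synthesis genes rose and 1 fell (13 and 1 within the list, camera adjusted p = 7.5e-08, estimated-correlation adjusted p = 0.17), with Alas2 (12.59 ± 0.65) and Fech (7.30 ± 0.39). 22 of 22 erythroid membrane genes rose (22 within the list, camera adjusted p = 2.0e-13, estimated-correlation adjusted p = 0.23), with Sptb (8.73 ± 0.30). 17 of 22 late erythroid ubiquitin-proteasome genes rose and 2 fell (17 and 2 within the list, camera adjusted p = 1.3e-06, estimated-correlation adjusted p = 0.39), with Ube2o (8.51 ± 0.50) and Trim10 (11.55 ± 0.52). 25 of 25 ribosome biogenesis genes fell (25 within the list, camera adjusted p = 1.6e-07, estimated-correlation adjusted p = 0.17), with Ddx21 (-4.99 ± 0.19) and Polr1a (-4.53 ± 0.20). 1 of 19 stem and progenitor genes rose and 14 fell (1 and 14 within the list, camera adjusted p = 7.3e-04, estimated-correlation adjusted p = 0.39), with Myb (-6.36 ± 0.23) and Myc (-6.35 ± 0.29). Glul rose by 3.80 ± 0.28. With each triplicate summed the count was 4671.

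The knockout series compares GS-KO with WT cells of the same gate, and Glul (chromosome 1, 153899944 to 153909723, plus strand, mm10) was read first in each library. In BFU-E Glul stood at 122 ± 2.91 CPM in WT and 98.8 ± 2.41 in GS-KO (SD, n = 3 each), in CFU-E at 86 ± 3.16 and 36 ± 1.39, in ERY-I-II at 110.1 ± 5.02 and 14.9 ± 1.92, in ERY-III-VI at 159 ± 7.44 and 19.2 ± 2.91 and in ERY-V-VI at 254 ± 12.2 and 23.3 ± 0.882. Each GS-KO library lay below each WT library of its gate, which chance gives in 10% of splits of 3 against 3 in either direction. The log2 fold changes of Glul were -0.29 ± 0.05, -1.26 ± 0.06, -2.77 ± 0.10, -3.22 ± 0.09 and -4.73 ± 0.09 in that order, and the change differed between stages (interaction adjusted p = 1.7e-39). Epor (chromosome 9, 21958897 to 21963506, minus strand) was also lower in each stage, by log2 fold changes of -0.88 ± 0.08, -1.08 ± 0.06, -0.63 ± 0.07, -1.24 ± 0.06 and -1.82 ± 0.12.

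**Figure D1:**
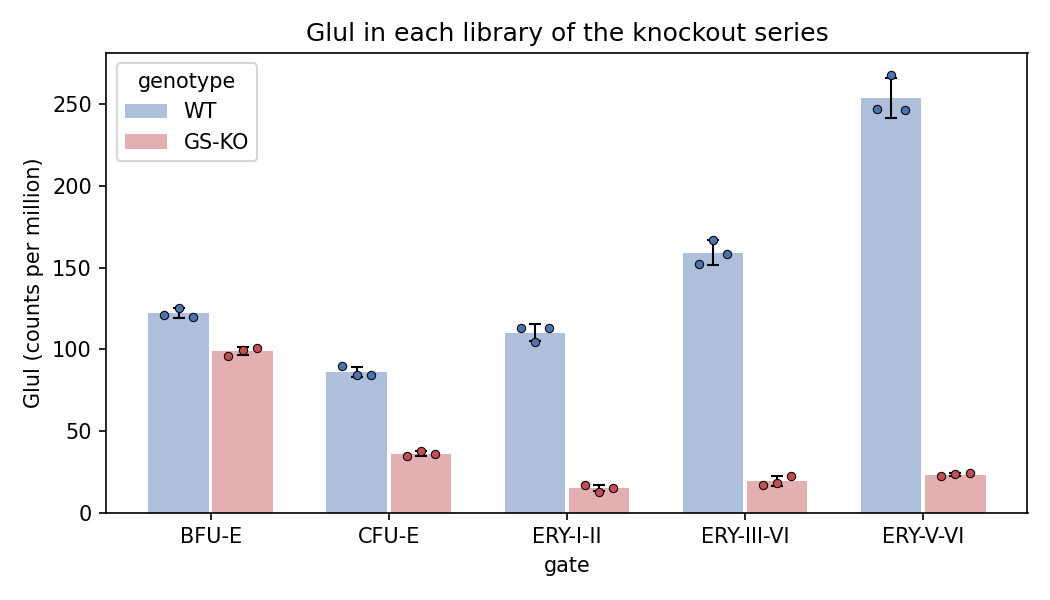
CPM of Glul in each of the 30 libraries of the knockout series on a linear axis from 0, by gate and genotype, with bars at the mean of 3 libraries and error bars of 1 SD. The mean fell from 122 in WT to 98.8 in GS-KO BFU-E and from 254 in WT to 23.3 in GS-KO ERY-V-VI.

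Genes changed in the same direction in all 5 stages numbered 665 higher and 31 lower in GS-KO of 8913 tested in each, against 4.4 and 1.2 expected if the stages were independent. The lower ones included Glul, Epor and Tspo2, a gene of the translocator protein family. Among the higher ones were markers of neutrophils: their summed CPM went from 36.1 to 7854 in BFU-E, 31.6 to 4861 in CFU-E, 124 to 6935 in ERY-I-II, 282 to 11074 in ERY-III-VI and 696 to 15008 in ERY-V-VI (means of 3 libraries). The 3 libraries of each group differed less than Xist-positive stage libraries of one gate (chi-square per degree of freedom 1.29 to 6.25 over pairs of one group, median 2.06, against 7.63 to 98, median 44.9), so that the counts of changed genes below rest on a spread that may not include differences between mice. With each triplicate summed to 1 library and the spread taken from the stage libraries, edgeR's likelihood ratio test called 52 genes in BFU-E, 21 in CFU-E, 2 in ERY-I-II, 22 in ERY-III-VI and 0 of 3103 in ERY-V-VI, where 86 had an unadjusted p below 0.05 and no other tool was run on these sums.

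**Figure D2:**
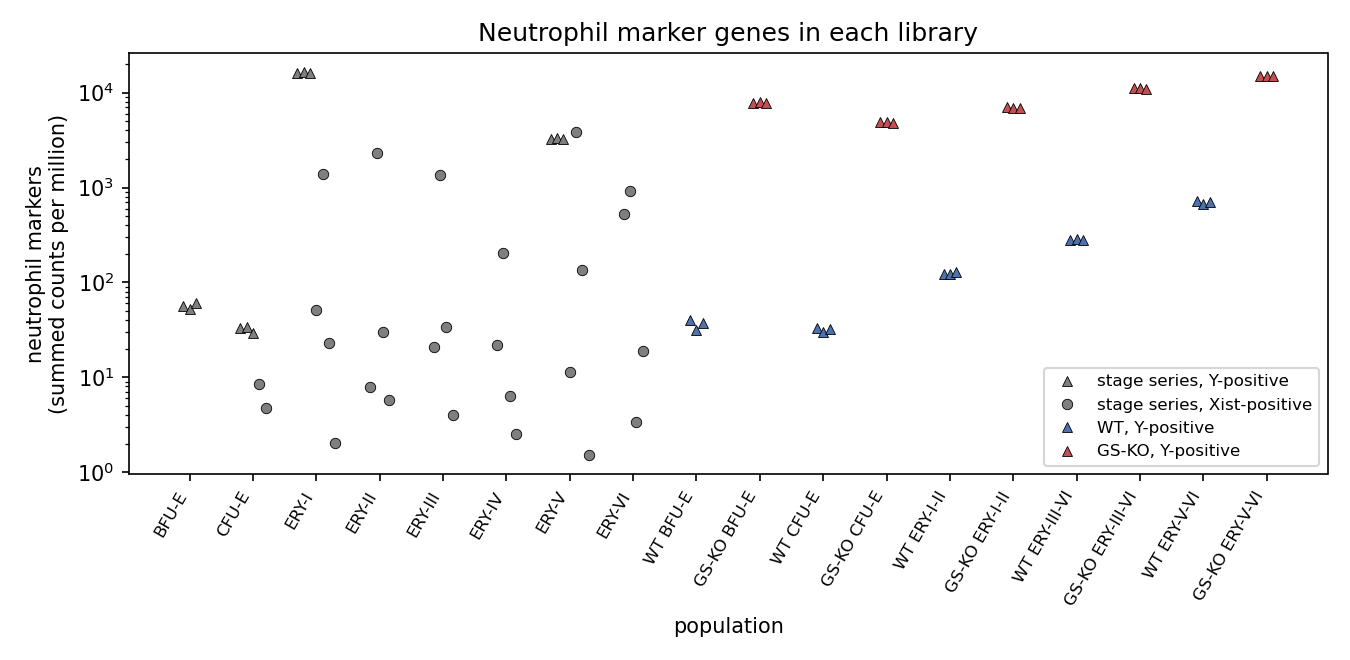
Summed CPM of the neutrophil marker genes in each of the 68 libraries, on a log10 axis, by population and genotype. In the knockout series the GS-KO means ran from 4861 to 15008 and the WT means from 31.6 to 696.

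In BFU-E, GS-KO libraries held more late erythroid transcripts, along with those of other cells. Hba-a1 rose from 4.22 ± 1.25 to 298 ± 15.2 CPM and Slc4a1 from 3.99 ± 1.09 to 247 ± 12.2 CPM (n = 3 each). Of 11356 genes tested 1752 were higher and 975 lower in GS-KO. Among genes of at least 5 CPM the largest falls were those of Tspo2 (-1.90 ± 0.19) and Ccnb1ip1 (-1.35 ± 0.18) and of RNA genes of ribonuclease P, Rprl1 (-1.22 ± 0.11) and Rprl2 (-1.19 ± 0.17). Late erythroid groups rose. 4 of 4 globin genes rose (4 within the list, camera adjusted p = 1.3e-06), with Hba-a2 (6.97 ± 0.26) and Hbb-b1 (5.82 ± 0.07). 12 of 22 erythroid membrane genes rose and 2 fell (13 and 2 within the list, camera adjusted p = 4.7e-05, estimated-correlation adjusted p = 0.054), with Tmod1 (4.20 ± 0.48) and Dmtn (2.94 ± 0.17). 7 of 14 heme synthesis genes rose (7 within the list, camera adjusted p = 0.0021, estimated-correlation adjusted p = 0.059), with Alas2 (4.90 ± 0.12) and Slc25a37 (1.64 ± 0.07). Markers of other cells rose in the same libraries. 19 of 19 neutrophil marker genes rose (19 within the list, camera adjusted p = 1.0e-25), for example S100a9 (8.80 ± 0.06) and Mpo (6.65 ± 0.04). 11 of 13 monocyte and macrophage marker genes rose (11 within the list, camera adjusted p = 1.2e-09), for example Lyz2 (7.05 ± 0.08). 14 of 15 B cell marker genes rose (14 within the list, camera adjusted p = 2.2e-10), for example Dntt (6.33 ± 0.27). 2 of 3 T and NK cell marker genes rose (2 within the list, camera adjusted p = 0.0039, estimated-correlation adjusted p = 0.099). 5 of 6 stromal and endothelial marker genes rose (5 higher and 1 lower within the list, camera adjusted p = 0.0023, estimated-correlation adjusted p = 0.066). 13 of 24 stem and progenitor genes rose and 3 fell (15 and 4 within the list, camera adjusted p = 1.3e-04), with Cd34 (3.08 ± 0.18). Early response genes joined them. 7 of 14 immediate early genes rose (7 within the list, camera adjusted p = 3.5e-05), with Btg2 (4.35 ± 0.25) and Zfp36 (2.08 ± 0.28). 11 of 20 unfolded protein response genes rose (12 within the list, camera adjusted p = 7.9e-05), with Edem1 (0.89 ± 0.09) and Xbp1 (0.61 ± 0.09).

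Changes in ribosomal and mitochondrial genes of GS-KO BFU-E were small and downward. 28 of 34 cytosolic ribosomal protein genes fell (28 within the list, camera adjusted p = 1.9e-07), with Rps18 (-0.32 ± 0.04) and Rpl6 (-0.23 ± 0.03). 18 of 25 ribosome biogenesis genes fell (20 within the list, camera adjusted p = 2.2e-06), with Wdr12 (-0.22 ± 0.04) and Fbl (-0.21 ± 0.04). 15 of 40 nuclear-encoded respiratory chain genes fell (17 within the list, camera adjusted p = 1.5e-05, estimated-correlation adjusted p = 0.050), with Sdhb (-0.32 ± 0.05) and Cox5b (-0.24 ± 0.04). 5 of 24 TCA cycle genes fell (5 within the list, camera adjusted p = 9.3e-04, estimated-correlation adjusted p = 0.050), with Fh1 (-0.22 ± 0.05). In glutamine metabolism 7 of 24 glutamine and glutamate enzyme genes fell (7 within the list, camera adjusted p = 0.057), a list called without replicate 1 of GS-KO (adjusted p = 0.044) or of WT (adjusted p = 0.031), with Asns (-0.22 ± 0.05), Cad (-0.20 ± 0.03) and Oat (-0.20 ± 0.04). In sugar and sterol metabolism 9 of 19 glycolysis genes rose and 4 fell (9 and 4 within the list, camera adjusted p = 0.011, estimated-correlation adjusted p = 0.084), with Pkm, a pyruvate kinase gene also expressed in white cells, and Hk2, a hexokinase gene, at 2.59 ± 0.08 and 1.13 ± 0.10. 4 of 20 sterol synthesis genes rose (4 within the list, camera adjusted p = 0.010, estimated-correlation adjusted p = 0.084).

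In CFU-E 1941 genes were higher and 1250 lower in GS-KO of 10859 tested (n = 3 each). Globin genes again rose, Hba-a1 from 11.8 ± 1.53 to 212 ± 5.77 CPM. 4 of 4 globin genes rose (4 within the list, camera adjusted p = 1.7e-06). Most heme synthesis enzymes did not follow. 2 of 14 heme synthesis genes rose and 8 fell (2 and 10 within the list, camera adjusted p = 0.013, estimated-correlation adjusted p = 0.22, median -0.15, mean 0.22, camera direction down) while fry gave the direction up, with rises of Alas2 (3.90 ± 0.10) and Slc25a37 (1.40 ± 0.06) and falls of Uros (-0.39 ± 0.09) and Alad (-0.23 ± 0.03). Division genes fell by small amounts. 22 of 30 DNA replication genes fell (24 within the list, camera adjusted p = 3.8e-08), for example Rfc4 (-0.26 ± 0.05) and Cdc6 (-0.23 ± 0.03). 1 of 30 mitosis genes rose and 14 fell (1 and 15 within the list, camera adjusted p = 3.2e-04, estimated-correlation adjusted p = 0.056), for example Bub1 (-0.20 ± 0.05) and Plk1 (-0.18 ± 0.04). In glutamine metabolism 2 of 22 glutamine and glutamate enzyme genes rose and 9 fell (2 and 13 within the list, camera adjusted p = 4.5e-04, estimated-correlation adjusted p = 0.061), with Asns (-0.21 ± 0.03) and Gclm (-0.16 ± 0.03) beside a rise of glutamate dehydrogenase, Glud1 (0.28 ± 0.05). 11 of 24 TCA cycle genes fell (11 within the list, camera adjusted p = 3.0e-04, estimated-correlation adjusted p = 0.073), with Pcx (-0.36 ± 0.09) and Idh3a (-0.19 ± 0.03). Beside Glul and Epor large falls among genes of at least 5 CPM were those of Rap1gap (-1.37 ± 0.11) and Mid1 (-1.08 ± 0.15). In the same libraries 19 of 19 neutrophil marker genes rose (19 within the list, camera adjusted p = 2.3e-21), with Mpo (6.88 ± 0.05). 9 of 10 monocyte and macrophage marker genes rose (9 within the list, camera adjusted p = 5.1e-06), with Lyz2 (7.18 ± 0.10). Beside them 18 of 22 stem and progenitor genes rose (19 higher and 1 lower within the list, camera adjusted p = 1.1e-09), with Cd34 (5.93 ± 0.31) and Spi1 (5.01 ± 0.25). 9 of 18 glycolysis genes rose and 2 fell (10 and 2 within the list, camera adjusted p = 0.0014, estimated-correlation adjusted p = 0.076), with Pkm (6.40 ± 0.15) and Hk2 (1.97 ± 0.14).

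In ERY-I-II 2278 genes were higher and 1739 lower in GS-KO of 9954 tested (n = 3 each). Library totals gave 1792 higher and 3179 lower with the median of all genes at -0.13. Alas2 rose from 1757 ± 21.2 to 3704 ± 12.6 CPM and Bnip3l from 262 ± 9.16 to 504 ± 25.9 CPM. Red cell genes rose. 4 of 4 globin genes rose (4 within the list, camera adjusted p = 7.3e-05, estimated-correlation adjusted p = 0.051), with Hbb-b1 (1.16 ± 0.01) and Hba-a2 (0.84 ± 0.02). 19 of 22 erythroid membrane genes rose and 2 fell (19 and 2 within the list, camera adjusted p = 7.7e-06, estimated-correlation adjusted p = 0.051), with Epb4.1 (1.42 ± 0.02). 12 of 21 late erythroid ubiquitin-proteasome genes rose and 4 fell (12 and 4 within the list, camera adjusted p = 0.0055, estimated-correlation adjusted p = 0.082), with Ube2o (1.42 ± 0.02) and Ube2h (1.24 ± 0.07). Translation and respiration genes fell. 34 of 34 cytosolic ribosomal protein genes fell (34 within the list, camera adjusted p = 1.3e-13), with Rps18 (-0.49 ± 0.05) and Rps2 (-0.47 ± 0.05). 31 of 40 nuclear-encoded respiratory chain genes fell (36 within the list, camera adjusted p = 1.7e-09), with Ndufc2 (-0.57 ± 0.11) and Ndufa5 (-0.47 ± 0.08). 1 of 24 TCA cycle genes rose and 17 fell (1 and 19 within the list, camera adjusted p = 6.9e-05), with Fh1 (-0.47 ± 0.09) and Cs (-0.30 ± 0.04). 21 of 30 DNA replication genes fell (21 within the list, camera adjusted p = 9.9e-06, estimated-correlation adjusted p = 0.051), with Mcm5 (-0.28 ± 0.03). In glutamine metabolism 3 of 22 glutamine and glutamate enzyme genes rose and 9 fell (3 and 9 within the list, camera adjusted p = 0.017, estimated-correlation adjusted p = 0.15), with the glutamate dehydrogenase and CTP synthase genes Glud1 (0.72 ± 0.12) and Ctps2 (1.40 ± 0.30) higher, and the glutamine carrier gene and the heavy and light chain genes of an amino acid exchanger rose, Slc1a5 (0.41 ± 0.05), Slc3a2 (0.62 ± 0.05) and Slc7a5 (0.58 ± 0.04). The largest fall was that of Bcat1, which makes glutamate from branched-chain amino acids, at -3.59 ± 0.39. In the same libraries 19 of 19 neutrophil marker genes rose (19 within the list, camera adjusted p = 3.1e-16). 9 of 9 B cell marker genes rose (9 within the list, camera adjusted p = 1.1e-05). 14 of 16 stem and progenitor genes rose and 1 fell (14 and 1 within the list, camera adjusted p = 2.5e-07), with Spi1 (5.88 ± 0.33) and Myb (1.06 ± 0.07). 9 of 12 interferon response genes rose and 1 fell (9 and 1 within the list, camera adjusted p = 7.4e-05, estimated-correlation adjusted p = 0.051), with Ifit1 (2.31 ± 0.28) and Isg15 (1.93 ± 0.13).

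In ERY-III-VI 3132 genes were higher and 2444 lower in GS-KO of 9981 tested (n = 3 each). Library totals gave 3957 higher and 1339 lower with the median of all genes at 0.21, and all groups in 1 fit 3145 and 3839. Kit rose from 2.21 ± 0.159 to 34.8 ± 0.688 CPM, and erythroid genes other than globins fell. 1 of 22 erythroid membrane genes rose and 21 fell (1 and 21 within the list, camera adjusted p = 5.7e-09), with Aqp1 (-0.57 ± 0.02) and Slc4a1 (-0.46 ± 0.02). 1 of 20 erythroid transcription factor genes rose and 18 fell (1 and 18 within the list, camera adjusted p = 6.5e-07), with Gata1 (-0.53 ± 0.04) and Klf1 (-0.50 ± 0.03). 1 of 14 heme synthesis genes rose and 12 fell (1 and 12 within the list, camera adjusted p = 1.3e-04, estimated-correlation adjusted p = 0.15), with Abcb6 (-0.49 ± 0.05) and Uros (-0.48 ± 0.05). Globin genes took 4.74 ± 0.0291% of counts in WT and 5.79 ± 0.129% in GS-KO. 3 of 4 globin genes rose and 1 fell (3 and 1 within the list, camera adjusted p = 0.77), with Hbb-b1 (0.16 ± 0.02) and Hba-a2 (-0.57 ± 0.02), while with all groups in 1 fit 0 rose and 2 fell, Hbb-b1 at -0.068. Division genes fell with them. 30 of 30 mitosis genes fell (30 within the list, camera adjusted p = 1.6e-10), with Aurkb (-0.55 ± 0.05) and Ccna2 (-0.51 ± 0.03). 27 of 30 DNA replication genes fell (28 within the list, camera adjusted p = 4.6e-10), with Ung (-0.57 ± 0.17) and Pcna (-0.50 ± 0.03). 23 of 25 ribosome biogenesis genes rose (23 within the list, camera adjusted p = 8.3e-06), with Rrp1b (3.38 ± 0.32) and Npm1 (1.05 ± 0.06). Single glutamate-linked genes (list result not given) included Psat1 (2.60 ± 0.28) and Glud1 (2.44 ± 0.17) higher and the glutathione synthesis genes Gclc (-0.53 ± 0.04) and Gclm (-0.38 ± 0.03) lower. Markers of other cells rose beside them. 19 of 19 neutrophil marker genes rose (19 within the list, camera adjusted p = 2.9e-14), for example S100a9 (5.48 ± 0.04). 14 of 14 B cell marker genes rose (14 within the list, camera adjusted p = 7.6e-06), for example Dntt (4.51 ± 0.27). 15 of 17 stem and progenitor genes rose (15 within the list, camera adjusted p = 2.6e-07), with Fli1 (4.47 ± 0.21) and Myb (2.62 ± 0.09).

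In ERY-V-VI 2110 genes were higher and 1924 lower in GS-KO of 9403 tested (n = 3 each). With library totals 7219 were higher and 361 lower and the median of all genes moved from 0.15 to 1.44, so that directions here are relative to the TMM scale. Alas2 fell from 22357 ± 405 to 7767 ± 32 CPM and Hba-a1 from 70887 ± 715 to 30697 ± 810.1 CPM, while Kit rose from 4.65 ± 0.96 to 58 ± 3.1 CPM. 22 of 22 erythroid membrane genes fell (22 within the list, camera adjusted p = 6.3e-14, list median 0.08 with library totals against -1.22), with Epb4.1 (-2.70 ± 0.01) and Mpp1 (-2.46 ± 0.05). 5 of 5 globin genes fell (5 within the list, camera adjusted p = 1.9e-05), with Hba-a2 (-3.59 ± 0.02) and Hbb-b1 (-2.60 ± 0.01). 12 of 14 heme synthesis genes fell (12 within the list, camera adjusted p = 2.1e-06, list median 0.44 with library totals against -0.85), with Fech (-2.36 ± 0.02) and Slc25a37 (-2.14 ± 0.02). 1 of 20 erythroid transcription factor genes rose and 16 fell (2 and 16 within the list, camera adjusted p = 4.5e-06, list median 0.58 with library totals against -0.72), with E2f2 (-2.08 ± 0.03) and Foxo3 (-1.75 ± 0.05). Clearance genes fell too. 2 of 24 autophagy and mitochondrial clearance genes rose and 18 fell (2 and 18 within the list, camera adjusted p = 2.3e-07), for example Bnip3l (-2.80 ± 0.03) and Gabarapl2 (-2.58 ± 0.11). 2 of 22 late erythroid ubiquitin-proteasome genes rose and 14 fell (2 and 14 within the list, camera adjusted p = 4.3e-06, estimated-correlation adjusted p = 0.076), for example Ubb (-3.57 ± 0.54) and Rnf10 (-2.81 ± 0.02). 9 of 12 interferon response genes fell (9 lower and 1 higher within the list, camera adjusted p = 3.1e-05), with Ifit1 (-2.28 ± 0.22) and Isg15 (-1.96 ± 0.11), opposite in direction to ERY-I-II. Genes of translation rose. 18 of 25 ribosome biogenesis genes rose (20 within the list, camera adjusted p = 6.6e-05, estimated-correlation adjusted p = 0.076), for example Fbl (2.92 ± 0.64) and Npm1 (1.26 ± 0.11). 20 of 34 cytosolic ribosomal protein genes rose and 1 fell (20 and 1 within the list, camera adjusted p = 0.0048, estimated-correlation adjusted p = 0.076), for example Rpl32 (1.31 ± 0.14) and Rps20 (0.86 ± 0.15). In the same libraries 19 of 19 neutrophil marker genes rose (19 within the list, camera adjusted p = 1.9e-09). 15 of 18 stem and progenitor genes rose and 1 fell (15 and 1 within the list, camera adjusted p = 7.3e-05), with Myb (2.63 ± 0.15) and Spi1 (2.89 ± 0.40), and as single genes Fh1 (1.85 ± 0.37) and Idh2 (1.39 ± 0.36) rose (mitochondrial lists not given). Globin genes took 19.7 ± 0.136% of counts in WT and 7.76 ± 0.0676% in GS-KO.

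The GS-KO effect differed between the 5 stages for 7379 of 12051 genes tested together (edgeR, interaction with 4 degrees of freedom). Alas2 was raised in BFU-E, at 4.90 ± 0.12, and lowered in ERY-V-VI, at -2.82 ± 0.02 (interaction adjusted p = 3.0e-65). Npm1, a ribosome assembly gene, rose in ERY-V-VI, at 1.26 ± 0.11, and differed there from BFU-E by 1.30 (adjusted p = 3.1e-24), and the interferon gene Ifit1 went from 2.31 ± 0.28 in ERY-I-II to -2.28 ± 0.22 in ERY-V-VI (adjusted p = 8.4e-18). With the triplicates summed and the spread taken from the stage libraries 22 genes passed.

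**Figure D3:**
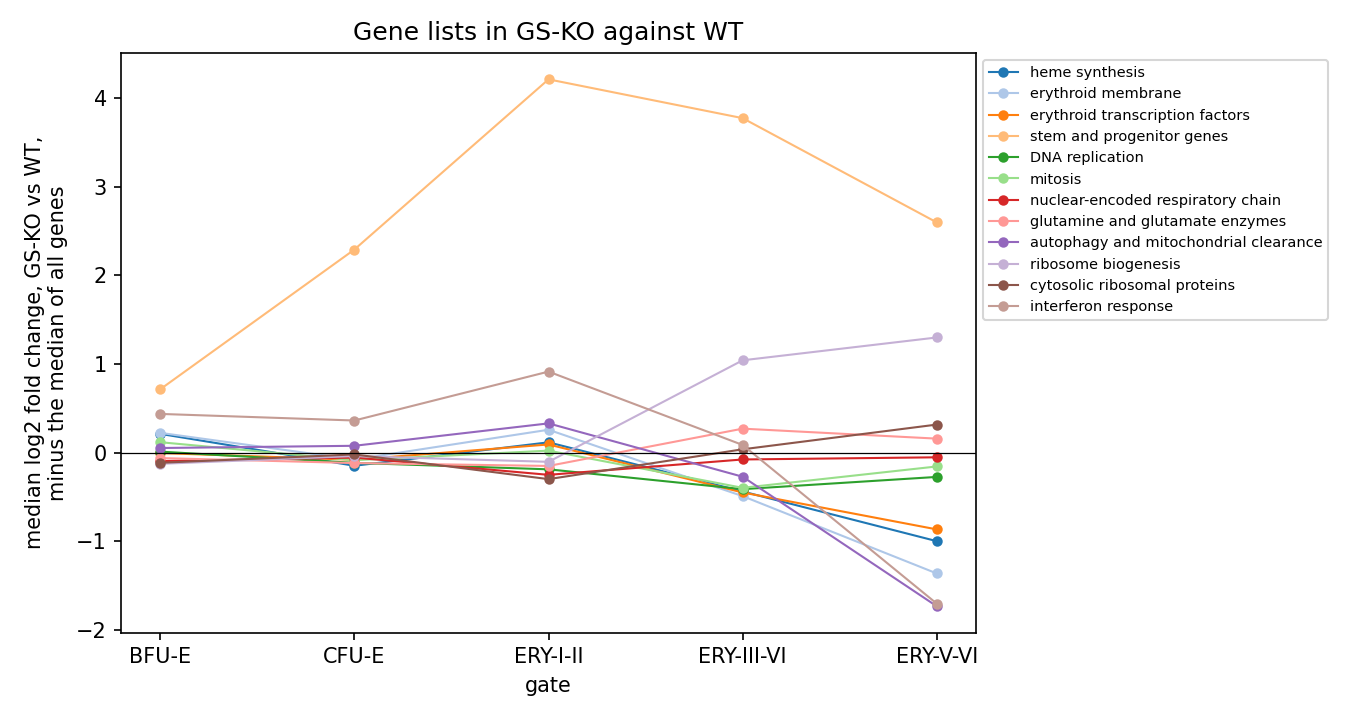
Median log2 fold change of 12 gene lists minus the median of all genes tested, in the 5 comparisons of GS-KO with WT (n = 3 each), 1 line per list and 1 dot per gate. The erythroid membrane list lay at 0.26 in ERY-I-II and at -1.37 in ERY-V-VI.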

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

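The tests of the 3 patterns weighed in this part were chosen after the results were seen, and the interaction test was planned. Among 168 groups of 4 to 7 libraries 16 held 1 library far from the rest, against 8.4 expected by chance at 1 in 20. Summed neutrophil markers stood out in replicate 2 of ERY-II at 2326 CPM, of ERY-III at 1340 CPM and of ERY-IV at 202 CPM, and macrophage markers in ERY-VI replicate 2 at 263 CPM. Progenitor genes stood out as Kit in ERY-III replicate 2 at 3.45 CPM, ERY-VI replicate 2 at 12.3 CPM and ERY-IV replicate 1 at 1.51 CPM, and Gata2 in ERY-II replicate 2 at 4.41 CPM and ERY-V replicate 1 at 12.9 CPM. CFU-E replicate 5 held more late erythroid transcripts than the other CFU-E libraries, with Hba-a1 at 96.4 CPM, Hba-a2 at 19.4 CPM and Slc4a1 at 108 CPM, and more B cell markers at 13.6 CPM. The others were Foxo3 in CFU-E replicate 4 at 54.7 CPM, Bnip3l in ERY-II replicate 3 at 582 CPM and Cdkn1a in ERY-VI replicate 1 at 5 CPM.

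The effect of GS-KO differed between gates for 7379 genes and for 16 of 18 landmark genes. As log2 effect in ERY-V-VI minus BFU-E the landmark values were -4.475 for Glul, -0.9797 for Epor, 2.506 for Kit, 0.9333 for Myc, -0.4847 for Gata2, -0.3246 for Gata1, -0.3761 for Klf1, -1.215 for Tfrc and -0.8449 for Mki67. The late erythroid ones were -7.752 for Alas2, -8.455 for Hbb-b1, -8.694 for Hba-a1, -10.56 for Hba-a2, -7.749 for Slc4a1, -2.865 for Bnip3l and -1.853 for Foxo3.

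The first pattern weighed is that marker genes of neutrophils and other blood cells were higher in all 5 GS-KO populations. RNA of other marrow cells in 1 shared composition may account for them, since the ratio of the B cell and of the macrophage increment to the neutrophil one ranged over 0.771 and 0.288 (log2) across the 5 gates, against 3.26 and 0.939 for these markers over the 6 stage-series samples with at least 1000 CPM of neutrophil markers. Switching on of neutrophil genes in erythroid cells says nothing of B cell markers, higher in 56 of 61 tests, so these do not test it. For the neutrophil markers such switched-on genes cannot be told apart from RNA of other cells, since B cell RNA may differ by sample: its log2 ratio (median 3.67 of 5 gates) lay within those between 2 Xist-positive stage libraries of one gate (median 2.88, highest 8.29). Nor can a sort or preparation that differed between the genotypes be told apart from a change in the marrow itself, since Y-positive ERY-I libraries without a knockout label reached a mean of 16243 CPM, and whether the loss of GS changes the make-up of the marrow is untested.

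The neutrophil list shares 0 genes with the other lists, and in the stage series 8 of its 19 genes passed the low-count filter in CFU-E against BFU-E. Its most abundant genes in GS-KO ERY-V-VI were Ngp at 3438 CPM and Mpo at 2438 CPM, against 156 and 147 CPM in WT. The cells were enriched by flow cytometry, which should remove neutrophils, but the labels do not name the antibodies.

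The second pattern is that erythroid genes were lower in GS-KO ERY-V-VI on the TMM scale. Dilution by RNA of other cells alone would lower the 22 erythroid membrane genes by 1 factor, and their log2 changes spread over 2.07, from -2.70 for Epb4.1 to -0.63 for Xk, but between 2 Xist-positive stage libraries of one gate they spread over 1.28 to 2.36 in ERY-V and 2.60 to 4.03 in ERY-VI, so it stays open. More immature erythroid cells in the gate may contribute, with a correlation of 0.432 across genes between this effect and ERY-I minus ERY-V of the stage series, and against ERY-II, ERY-III and ERY-IV the correlation was 0.33, 0.28 and 0.12. Genes are not independent replicates, and a slower maturation and a shifted gate cannot be told apart from these values.

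The third pattern is that Epor was lower in all 5 GS-KO populations. Dilution alone is argued against in BFU-E, CFU-E and ERY-I-II, where Epor minus the mean of Gata1 and Klf1 was -0.703 (log2, median of -0.975 to -0.565), beyond the differences between 2 Xist-positive libraries of CFU-E, ERY-I or ERY-II (13 pairs, median 0.267, highest 0.570). It stays open in ERY-III-VI and ERY-V-VI (median -1.03 of -0.726 and -1.34), since pairs within ERY-III to ERY-V had a median of 0.281 and reached 1.75 in ERY-V. The loss of 1 Epor allele in each GS-KO library would give about -1, and the values ran from -0.632 in ERY-I-II to -1.82 (TMM scale) in ERY-V-VI, where a different mix of stages may add to or offset it. A deleter strain with an insertion at Epor is in common use, but the labels name no strain, so this stays open.

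Other splits of the same libraries were counted as a check on chance. Replicates 1 to 3 of the Y-positive groups may be 1 sample each and other libraries pair up, so free splits cannot exclude chance. Such splits seldom reached the real count for ERY-I against CFU-E (4850, highest other 1569) and ERY-II against ERY-I (4679 and 3153). The same held for ERY-IV against ERY-III (987 and 529) and ERY-V against ERY-IV (617 and 9). For ERY-VI against ERY-V (394 and 453) 2 of 100 splits were as large. Summed triplicates gave, in order and without ERY-IV against ERY-III, 3088, 3958, 315 and 75 genes. Other splits gave at most 59, 841, 251 and 25. For CFU-E against BFU-E (4031 genes in 1 of 56 splits, highest other 0) and ERY-IV against BFU-E (8126 in 1 of 35, highest other 0) chance is left undecided, since with triplicates summed 4 and 5 splits are too few (real counts 105 and 4671, highest other 0 in each). The 1569 and the 3153 came from splits that nearly follow the library sets, and within the Xist-positive libraries the real counts were 4271 and 4086. The 453 parted ERY-V replicates 6 and 7 with ERY-VI replicates 3 and 4 from the others. For ERY-III against ERY-II chance cannot be excluded without the pairing, since 2 of 35 splits gave as many as the 14 genes. There 1110 came from replicates 3 and 4 against 1 and 2, as did the 529 above, and with the 453 these point to a structure of the samples. Splits that part as many pairs, 7 others in each comparison and too few to exclude chance, gave 0 genes there and in ERY-IV against ERY-III. With the replicate number as a block the real splits gave 778 and 1824 and these other ones 0. In ERY-I against CFU-E such splits gave at most 383. With the position of the Xist-positive libraries as a block ERY-II against ERY-I, ERY-V against ERY-IV and ERY-VI against ERY-V gave 5100, 1020 and 211 genes, and other splits parting all pairs 0.

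The 10 splits of each comparison within the knockout series are too few, with real counts of 2727, 3191, 4017, 5576 and 4034 for GS-KO against WT from BFU-E to ERY-V-VI and 7632 for WT CFU-E against BFU-E, and a highest other split of 0 in each. For the interaction chance is left undecided (7379 in 1 of 40 splits, highest other 7059), since all its groups are triplicates that may be 1 sample each, and 22 genes passed with these summed. The 7059 came from a split that kept the genotypes apart in 3 of the 5 gates, and 26 splits that kept them apart in 0 gates gave at most 1 gene.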

How the results depend on the processing

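The summed, Y-positive, Xist-positive, position block, library set and neutrophil-gene settings were chosen after seeing the data, the others before. All groups in 1 fit changed the counts most often: 380 genes for CFU-E against BFU-E, 2895 for ERY-I against CFU-E, 2511 for ERY-II against ERY-I, 0 for ERY-III against ERY-II (edgeR, 340 at an unadjusted p under 0.05), 231 for ERY-IV against ERY-III, 2257 for ERY-V against ERY-IV, 3340 for ERY-VI against ERY-V and 6945 for GS-KO ERY-V-VI. With library totals counts became 7421 for ERY-II against ERY-I, 0 for ERY-III against ERY-II (588 unadjusted), 634 for ERY-IV against ERY-III, 411 for ERY-V against ERY-IV, 2219 for ERY-VI against ERY-V and 7580 for GS-KO ERY-V-VI. For ERY-III against ERY-II RLE size factors and leaving out the abundant genes gave 0 (932 and 950 unadjusted) and DESeq2 275. DESeq2 gave 1184 for ERY-V against ERY-IV and 889 for ERY-VI against ERY-V. Limma-voom gave 7059 for CFU-E against BFU-E, 1974 for ERY-V against ERY-IV and 663 for ERY-VI against ERY-V, and no low-count filter 1018 for ERY-V against ERY-IV.

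With triplicates summed the counts were 105 for CFU-E against BFU-E, 3088 for ERY-I against CFU-E, 315 for ERY-V against ERY-IV, 75 for ERY-VI against ERY-V and 4671 for ERY-IV against BFU-E. Y-positive libraries alone gave 7303 for CFU-E against BFU-E and 9091 for ERY-I against CFU-E, and Xist-positive ones 406 for ERY-V against ERY-IV and 59 for ERY-VI against ERY-V, or 1020 and 211 with their position as a block. Both ended the call of the neutrophil list in ERY-V against ERY-IV (adjusted p = 0.19 and 0.087, against 3.8e-19 to 0.0012 under the other settings at the preset correlation). In the knockout series summed triplicates with the spread of the stage libraries gave 52, 21, 2, 22 and 0 genes from BFU-E to ERY-V-VI (edgeR, 86 unadjusted in the last) and 22 for the interaction. Without the neutrophil-associated genes GS-KO counts were 2082, 2447, 3402, 4844 and 3533, within 1.5 times the values given first. Camera with an estimated correlation called 47 lists in place of 215.

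The replicate number as a block gave 7300 for CFU-E against BFU-E, 778 for ERY-III against ERY-II, 1824 for ERY-IV against ERY-III and 1171 for ERY-V against ERY-IV. It also ended the calls of Tal1 in ERY-VI against ERY-V (log2 fold change -1.63, adjusted p = 0.059) and of the late erythroid ubiquitin-proteasome list in ERY-V against ERY-IV (adjusted p = 0.30). It changed no other call named in the report and moved no other count by more than 1.5 times. In ERY-II against ERY-I, ERY-V against ERY-IV and ERY-VI against ERY-V the libraries correlated by position and not by number, so the number is not their pairing. In the comparisons without a pairing by number the lowest correlation of same-numbered libraries ran from -0.62 in ERY-II against ERY-I to 0.0039 in GS-KO ERY-I-II, and in no comparison did each library correlate best with its own number.

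Leaving out 1 library gave 2291 to 4315 genes for CFU-E against BFU-E (2291 to 2318 without BFU-E replicate 1, 2 or 3), 0 for ERY-III against ERY-II without any 1 of the 8, 521 to 927 for ERY-IV against ERY-III (521 to 641 without ERY-III replicate 1, 2 or 3 or ERY-IV replicate 3), 127 to 971 for ERY-V against ERY-IV (127 to 390 without ERY-IV replicate 1, 2, 3 or 4 or ERY-V replicate 1, 2, 3 or 5, and 971 without ERY-V replicate 7) and 182 to 510 for ERY-VI against ERY-V (182 to 239 without ERY-VI replicate 1 or ERY-V replicate 1, 2, 3 or 5). In the other 10 results no library moved a count by more than 1.5 times. The cause was not tested. Leaving out 1 library ended 14 of 1014 list calls, those of the ERY-I marker lists named in the report, and added 2, of the glutamine list in GS-KO BFU-E. Genes whose call ended in this way were not named, so they give no check.

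Of calls of named genes 31 of 2570 were lost under the planned settings and 134 of 563 under the added ones, 91 of them with summed triplicates in the knockout series. Genes whose call changed direction were not named, except Hbb-b1 in GS-KO ERY-III-VI (-0.068 with all groups in 1 fit), so reversals among named genes give no check either. Of list results counted in the same way 17 of 1170 lost the call and 7 gained it under the planned settings, and 13 of 206 lost it under the added ones. Depth limits which genes pass the low-count filter, 5030 in ERY-VI against ERY-V and 10807 in CFU-E against BFU-E, but detected genes did not follow the totals alone: ERY-VI replicate 1 held 6904 genes at 3396874 counts and ERY-V replicate 3 held 9623 at 2018009. Depth itself was not varied.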

Other observations

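Along the stage series Glul stood at 114 ± 0.791 CPM in BFU-E, 99.9 ± 5.78 in CFU-E, 147 ± 15.6 in ERY-I, 251 ± 32.2 in ERY-II, 201.2 ± 14.9 in ERY-III, 322 ± 36.6 in ERY-IV, 360.4 ± 60.4 in ERY-V and 121 ± 32.9 in ERY-VI (mean ± SD). The last step passed no threshold on the TMM scale (adjusted p = 0.88). Myc, a growth regulator, went from 618 ± 15.6 to 3.98 ± 3.83 CPM between BFU-E and ERY-II, and Mki67, a gene of dividing cells, from 2593 ± 10.6 to 11420.0 ± 4019.6 in ERY-I, 15162 ± 7428 in ERY-II, 13352 ± 8722 in ERY-III and 366 ± 218 in ERY-VI. Foxo3, a transcription factor of late erythroid cells, stood at 175 ± 5.2 CPM in BFU-E and 597 ± 272 in ERY-V.

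In WT cells Glul was lowest in CFU-E and highest in ERY-V-VI, and Epor stood at 57.8 ± 1.4 CPM in BFU-E, 85.5 ± 6.56 in CFU-E and 103 ± 12.7 in ERY-V-VI. The ratio of Hba-a1 to Hba-a2, neighbours of nearly the same sequence, was 3.61 in WT and 7.67 in GS-KO ERY-V-VI, 4.69 and 7.81 in ERY-III-VI and 6.15 and 8.42 in ERY-I-II (means of 3 libraries). It fell in GS-KO CFU-E (9.36 and 6.18). In BFU-E (25.5 and 7.9) WT counts were too few to tell. Shared reads were not analysed.

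Libraries numbered 4 to 7 in ERY-I and ERY-V correlated by position with those numbered 1 to 4 of the neighbouring stages. The correlation of deviations at the same position ran from 0.53 to 0.70 between ERY-I and ERY-II, 0.25 to 0.43 between ERY-IV and ERY-V and 0.18 to 0.29 between ERY-V and ERY-VI, against at most 0.54, 0.34 and 0.15 at other positions. Globin genes took 0.987 to 9.99% of counts in the 7 ERY-I libraries.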
